A study of Mus musculus with 2 samples.

How the data were processed

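Chromatin accessibility was measured by DNase-seq in RAW264 cells, a mouse macrophage-like line that forms osteoclasts, the bone-resorbing cells, when given the cytokine RANKL (receptor activator of NF-kappaB ligand). In DNase-seq, nuclei are digested lightly with DNase I, and the short fragments released from open chromatin are sequenced. There were 2 libraries, 1 from cells without RANKL and 1 from cells given GST-tagged RANKL at 234 ng/ml for 24 hours. Per the labels' protocols, fragments of 100 to 500 bp were cut from a gel and sequenced on an Illumina instrument.

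The authors deposited 1 peak list per library, and each list gives a position and a score per peak. Per the submitters' processing notes, Bowtie2 2.0.0 and MACS2 were used and the genome build was mm9. The calling threshold, fragment-size setting, any control library and the definition of the score are not given in the sources used here. The score is the authors' own value for each peak. It started at 50.0 in both lists, and 15 and 40 peaks without and with RANKL carried exactly 3100. It was used only to rank and filter peaks within a list, because a score depends on sequencing depth and on the calling settings. Read depth is unknown, so values carry no depth-based interval.

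Positions fit mm9: on chromosome 1, 12 peaks without RANKL and 24 with RANKL lay past the last gene of the GRCm38 gene table supplied for the work. No mm9 genome or annotation was used here, and coordinates were not converted. For that reason 3 results planned before the data were examined were not computed. These were the annotation of peaks to promoters, exons and introns, the counts over 14 fixed gene lists, and the search for 16 sequence motifs. Sites are therefore named by position only, given 1-based on mm9.

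Overlaps were computed with bedtools 2.31.1, and other values with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and otherwise it was called a peak of one list only. The overlap was set beside 100 seeded random placements of the RANKL peaks on their own chromosomes, within the span that peaks of either list covered. Shares of peaks carry 95% Wilson intervals and ratios of peak counts 95% exact conditional Poisson intervals. Both cover counting error only and treat peaks as independent, which neighbouring peaks are not. With 1 library per group no test across replicates was possible, and no p-value was computed.

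The rule for named sites, fixed before the data were examined, took the 10 peaks with the highest score among the peaks of one list only, per list, on chromosomes 1 to 19 and X. The parts of that rule that named genes could not be applied. Isolated sites (outside clusters and over 5 kb from the other list), clusters (100 kb windows with at least 5 peaks of one list only) and a scan of 5 Mb windows for runs of 2 to 20 windows rich in RANKL peaks, with 100 seeded shuffles of the windows, were added after the data were seen. On simulated data, the overlap code classified 13492 of 13492 peaks correctly. Planted peaks lay either at the centre of a peak or far past all peaks, so partial overlaps and near misses were not tried. For the scan, 11 of 538 windows were given RANKL counts 1.8 times those expected from the ratio of chromosomes 1 to 19 and X (1.21). The scan found at least 7 of these 11 windows in 18 of 20 draws. The planted excess was larger than that of the segment reported below (ratio 1.93), and the draws varied by counting error only.

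Alternatives fixed before the data were examined were other overlap rules, the upper 50% of each list by score, equal numbers of peaks from each list, and chromosomes 1 to 19 and X alone. Merging peaks closer than 1 kb, windows of 500 bp around each peak centre, and leaving out the chromosome 3 segment, the clusters and chromosomes M and Y were added after the data were seen.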

Results

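Open chromatin was mapped in undifferentiated RAW264 macrophage-like cells and in RAW264 cells given RANKL for 24 hours, to find which DNase-hypersensitive sites are present before and after the start of osteoclast formation. Each condition had 1 library. No value below has a replicate error, and differences between the lists describe these 2 libraries. The list without RANKL held 13492 peaks covering 25.4 Mb, and the list with RANKL held 16447 peaks covering 4.83 Mb. Peaks without RANKL had a median width of 1738 bp (quartiles 1423 and 2120 bp). Peaks with RANKL had a median width of 233 bp (quartiles 160 and 367 bp), a 7.46-fold difference. The narrowest peak without RANKL, at 496 bp, was wider than 88.1% of the peaks with RANKL.

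**Figure D1:**
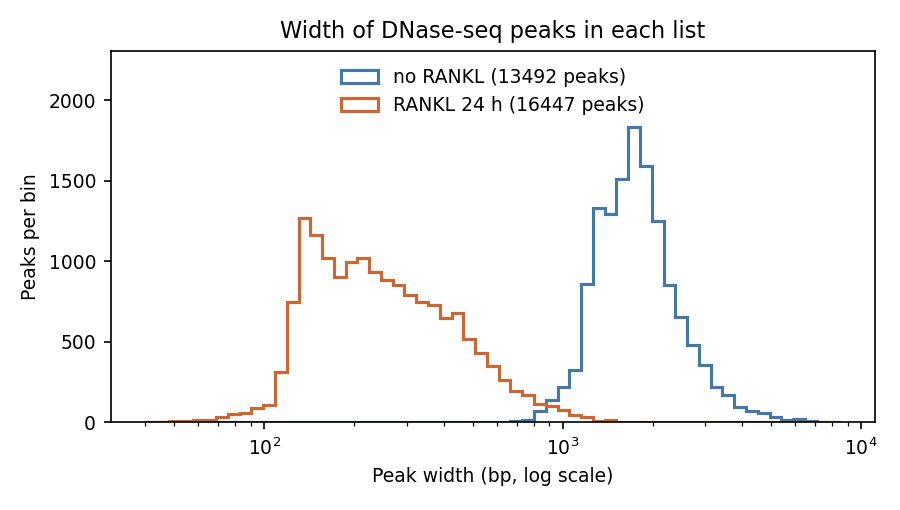
Histogram of peak width in bp on a log axis for the 13492 peaks without RANKL and the 16447 peaks after RANKL for 24 hours, with the number of peaks per bin on the vertical axis. The distributions hardly overlap, with medians of 1738 and 233 bp.

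The first comparison asked how many hypersensitive sites the 2 states had in common. Within each list, most peaks overlapped a peak of the other list. Sites called in 1 state or the other still outnumbered those found in both. There were 5306 peaks of one list only without RANKL and 5634 with RANKL, against 8186 shared peaks without RANKL. Of the peaks without RANKL, 8186 (60.7%, interval 59.8 to 61.5%) overlapped a peak with RANKL, against a mean of 1.49% and a maximum of 1.70% over 100 random placements. Of the peaks with RANKL, 10813 (65.7%, interval 65.0 to 66.5%) overlapped a peak without RANKL, against a mean of 1.245% in random placements. The numbers differ between the lists because 2255 broad peaks (16.7%) each overlapped 2 or more of the narrow RANKL peaks, while 5931 overlapped exactly 1. Broad peaks that overlapped 3 or more RANKL peaks had a median score of 188 in their list, those with 1 had 121, and those with none had 73.2. Their median widths went the same way, at 2433.5, 1806 and 1522 bp, and a wider peak has more room for several narrow ones. At the 5931 sites with 1 peak in each list, the RANKL peak lay wholly inside the broad peak in 5914 cases (99.7%), and the median distance between the peak centres was 153 bp. With the requirement that the overlap fill 50% of both peaks, the shared part was 0.348% of the list without RANKL and 0.286% of the list with RANKL.

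The strongest sites of either state were nearly all present in the other. In the highest 10% of the list without RANKL by score, 1336 of 1349 peaks (99.0%, interval 98.4 to 99.4%) overlapped a RANKL peak. In its lowest 10%, 344 of 1350 did (25.5%, interval 23.2 to 27.9%). In the RANKL list, 1567 of 1644 peaks of the highest 10% (95.3%, interval 94.2 to 96.2%) and 563 of 1645 of the lowest 10% (34.2%, interval 32.0 to 36.6%) overlapped a peak without RANKL. With each list cut into 10 equal parts by score, the share was higher in every successive part of both lists.

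**Figure D2:**
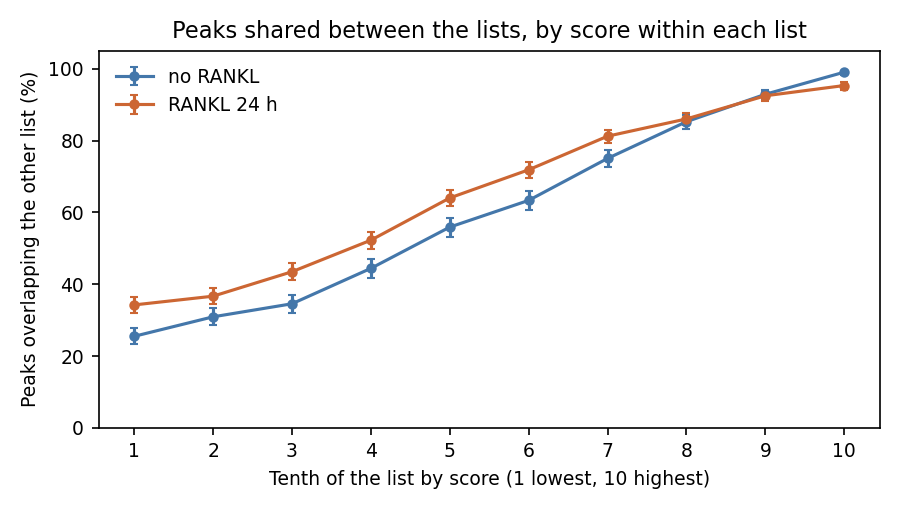
Percent of peaks that overlap the other list by at least 1 bp (vertical axis) in each of 10 equal parts of a list by the authors' score (horizontal axis, 1 lowest), for the lists without and with RANKL, with 95% Wilson intervals as bars. The share goes from 25.5% to 99.0% without RANKL and from 34.2% to 95.3% with RANKL.

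The second comparison asked which sites were called in 1 state only. Without RANKL, 5306 peaks (39.3%, interval 38.5 to 40.2%) had no RANKL peak on them, and 5634 RANKL peaks (34.3%, interval 33.5 to 35.0%) had no counterpart without RANKL. The first set lay at a median of 25.2 kb from the nearest RANKL peak, and the second at a median of 34.1 kb from the nearest peak without RANKL. Some gap follows from the definition of these sets. The gap expected for peaks placed at random was not computed, so the medians do not show whether the sites lay far from the other list. Sites of both sets were mostly weak. Peaks found only without RANKL had a median score of 73.2, against 132 for the shared peaks of that list, and RANKL-only peaks had a median of 58.0, against 91.9 for the shared RANKL peaks. Since weak peaks lie near the calling threshold, a peak missing from one list does not show that the site was closed there.

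Strong sites found only without RANKL were few: the highest 10% of that list by score held 13, of which 1 lay in a cluster, a 100 kb window with at least 5 such sites. The highest score among them, 256, belonged to a site on chromosome 7 at 117307390 to 117310260, with the nearest RANKL peak 41.8 kb away. A site on chromosome 2 at 181315086 to 181317179 scored 252 and lay 59.8 kb from the nearest RANKL peak. The site at 22055116 to 22057103 on chromosome 5 scored 237, with a gap of 75.9 kb. On chromosome 4, the site at 116861735 to 116863977 scored 236 and was the one in a cluster, with 5 such sites in its window. Chromosome 17 held 2 of the 10 highest-scoring sites on chromosomes 1 to 19 and X, at 66449879 to 66451977 (score 236) and at 35088758 to 35090541 (score 234). The remaining sites lay on chromosome 11 at 113508920 to 113511669 (score 230), chromosome 6 at 125522115 to 125523846 (score 229), chromosome 7 at 52240772 to 52243457 (score 229) and chromosome 1 at 39591663 to 39593258 (score 227). All 10 were in the highest 10% of their list.

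The strongest RANKL-only sites were, in contrast, gathered in a few places. Sequence present in many copies, which can gather reads from elsewhere, cannot be told apart here from a response to RANKL at these places. On chromosomes M and Y, 2 and 1 RANKL-only peaks had a score of 3100. Of the 10 with the highest scores on chromosomes 1 to 19 and X, 5 lay in 1 window near the start of the chromosome 9 sequence. Their positions were 3005895 to 3005978 (score 2734), 3032336 to 3032506 (score 2419), 3037995 to 3038082 (score 2080), 3031990 to 3032075 (score 687) and 3034174 to 3034261 (score 516), and each was within 2.64 kb of a broad peak without RANKL. On chromosome 11, 2 sites at 3091052 to 3094390 (score 931) and 3084250 to 3085710 (score 667) lay 52.3 and 61.0 kb from the other list. On chromosome X, 2 sites lay near the end of the sequence, at 166430005 to 166430069 (score 929) and 166432762 to 166433030 (score 711). They were 0.98 and 3.74 kb from the other list. The last of the 10 lay on chromosome X at 4545399 to 4545456 (score 494), 2680 kb from the nearest peak without RANKL. Of these 10, the peaks on chromosome 9 were 84 to 171 bp wide and those on chromosome X 58 to 269 bp. The 2 on chromosome 11 were 3339 and 1461 bp wide. Shared RANKL peaks had a median width of 294 bp. In all, 329 RANKL-only peaks (5.84%, interval 5.26 to 6.48%) fell in 37 windows of 100 kb with at least 5 such peaks, against 54 peaks (1.02%, interval 0.781 to 1.33%) in 10 windows for the list without RANKL. The fullest of these windows held 29 RANKL-only peaks on chromosome Y (2850742 to 2900353), 28 on chromosome 11 (3003951 to 3100065), 23 on chromosome 1 (85203165 to 85293918) and 22 on chromosome 8 (19917921 to 19985963). The spans on chromosomes 1 and 8 also held 3 and 10 peaks without RANKL, and those on chromosomes Y and 11 held 0. For the list without RANKL no window held more than 6, as on chromosome 12 at 113912498 to 114001126 and on chromosome 17 at 28300301 to 28371033. These windows were chosen after their values were seen. Closely spaced narrow peaks can add to the RANKL cluster counts. Merging peaks closer than 1 kb left 5344 RANKL-only regions of 5634 peaks, and 5261 of 5306 without RANKL. Clusters were not counted on merged peaks.

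Outside clusters and over 5 kb from any peak without RANKL, the highest-scoring RANKL-only sites on chromosomes 1 to 19 lay on chromosome 1 at 87511244 to 87511462 (score 393), chromosome 10 at 54608325 to 54608403 (score 291), chromosome 7 at 29279143 to 29279339 (score 288) and chromosome 10 at 7192483 to 7192616 (score 278). These isolated sites were also chosen after the values were seen. The highest 10% of the RANKL list held 77 RANKL-only sites, of which 42 lay in clusters, 18 lay on chromosomes M or Y, and 28 lay outside clusters on chromosomes 1 to 19 or X. Some of the sites on chromosome Y are counted among the clusters too.

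The third comparison set the 2 lists side by side by chromosome. Over all chromosomes the RANKL list held 1.22 peaks for each peak without RANKL, and on chromosomes 1 to 19 other than chromosome 3 this ratio went from 1.08 to 1.42. With peaks closer than 1 kb merged, a setting added after the data were seen, the lists held 13624 regions with RANKL and 13418 without, a ratio of 1.02 (interval 0.991 to 1.04), so that the overall surplus of RANKL peaks lay in closely spaced peaks. Chromosome 3 held 700 peaks without RANKL and 1196 with RANKL, a ratio of 1.71 (interval 1.56 to 1.88). Its share of RANKL-only peaks, 45.3% (interval 42.5 to 48.1%), was above that of the other 18 autosomes (27.3 to 39.7%), and its share of peaks found only without RANKL, 32.7% (interval 29.3 to 36.3%), was below theirs (36.1 to 42.4%). The intervals of the nearest autosomes overlapped both, as on chromosome 13 (RANKL-only 36.2 to 43.3%) and on chromosome 8 (found only without RANKL 32.5 to 39.9%). Chromosome 1 had the next highest autosomal ratio, at 1.42 (interval 1.30 to 1.55). Chromosome X had few peaks in either list, 113 without and 204 with RANKL, a ratio of 1.81 (interval 1.43 to 2.29), and 56.4% of its RANKL peaks (interval 49.5 to 63.0%) were RANKL-only. Its window from 120 to 125 Mb alone held 16 peaks without and 70 with RANKL, 35 of the latter RANKL-only. Chromosome Y had 12 and 78 peaks, and the mitochondrial genome 1 and 5.

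**Figure D3:**
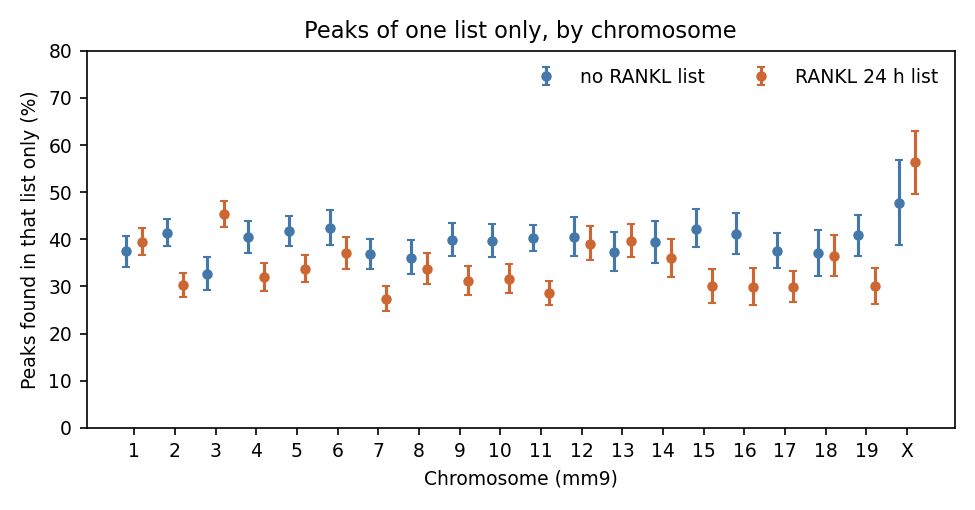
Percent of each list's peaks with no overlap in the other list (vertical axis) by mm9 chromosome (horizontal axis), as points with 95% Wilson intervals, for the lists without and with RANKL. Among the autosomes chromosome 3 has the highest RANKL-only share, 45.3%, and the lowest share found only without RANKL, 32.7%.

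Along chromosome 3 the additional RANKL peaks were not spread evenly. A scan of 5 Mb windows over chromosomes 1 to 19 and X, added after the data were seen, placed the strongest excess of RANKL peaks between 55 and 130 Mb of chromosome 3. This segment held 471 peaks without RANKL and 909 with RANKL, a ratio of 1.93 (interval 1.72 to 2.16). The rest of chromosome 3 held 229 and 287 peaks, a ratio of 1.253 (interval 1.050 to 1.498), close to the 1.21 of chromosomes 1 to 19 and X together. Within the segment, the window from 105 to 110 Mb held 55 and 129 peaks and the window from 95 to 100 Mb held 84 and 140. With peaks closer than 1 kb merged, the ratio was 1.63 in the segment (interval 1.45 to 1.84), 1.05 in the rest of chromosome 3 (interval 0.871 to 1.26) and 1.02 over all chromosomes.

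**Figure D4:**
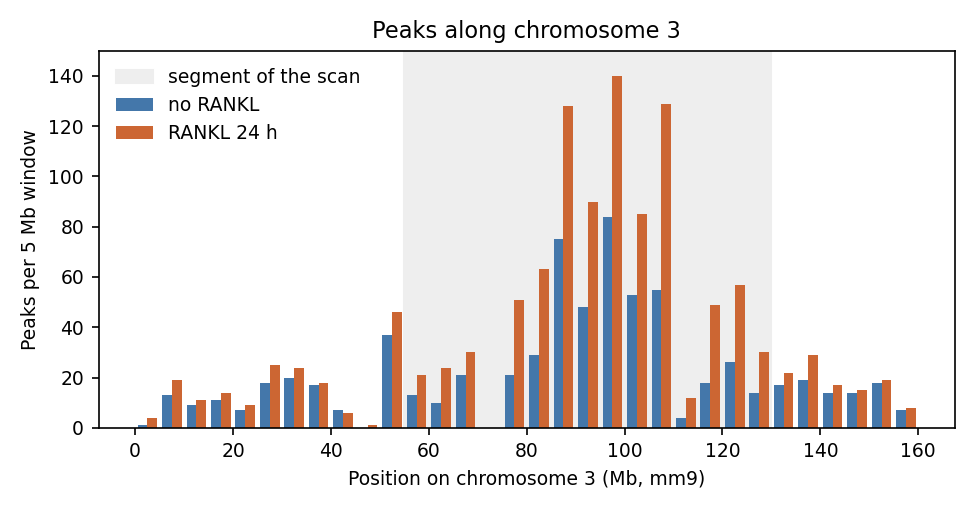
Number of peaks per 5 Mb window (vertical axis) along chromosome 3 in Mb on mm9 (horizontal axis), as bars for the lists without and with RANKL, with the segment found by the scan shaded. Between 55 and 130 Mb the RANKL list has 909 peaks against 471, and outside it 287 against 229.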

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

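Of 38 alternative values, 20 stayed within 1.5 times the reported count or within the counting interval of the reported share. The choice that mattered most was a reciprocal overlap of 50%, which left 13445 peaks without RANKL and 16400 with RANKL unshared (shared 0.348% and 0.286%). This follows from the widths, since a peak of 233 bp cannot fill 50% of a peak of 1738 bp. The upper 50% of each list by score holds 6746 and 8224 peaks by construction. Of these, 1140 and 1203 had no overlap in the whole other list, and with both lists so reduced 68.7% and 67.4% were shared. With equal numbers of peaks from each list, 56.9% of the peaks without RANKL and 72.6% of those with RANKL were shared, and 3702 RANKL peaks were unshared, because the weakest RANKL peaks were left out. Counting a peak of the other list within 1 kb as shared gave 66.7% for the RANKL list. Among the settings added after the data were seen, merging peaks closer than 1 kb gave 60.8% for the RANKL list, 500 bp windows around the centres gave 56.2% without and 56.6% with RANKL, and leaving out the chromosome 3 segment, the clusters and chromosomes M and Y gave 67.6% for the RANKL list. Allowing 1 kb can only raise a share, and clusters by definition hold peaks of one list only, so leaving them out raises it too. The cause of the other smaller shifts was not tested. Annotation, gene list and motif alternatives were not run, and no replicate could be left out. Unknown read depth limits every statement about sites missing from one list.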

Other observations

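The shuffle of windows and the test of whether clustered peaks lie near the other list were set out before their results were seen, and the other tests here were chosen after the results they bear on, or values close to them, had been seen. Outside the segment of chromosome 3, 372 windows of 5 Mb held at least 10 peaks without RANKL, and the 5 with the highest and the 5 with the lowest ratio of RANKL peaks are given here. The highest were chromosome X from 120 to 125 Mb (16 peaks without RANKL and 70 with RANKL), chromosome 9 from 0 to 5 Mb (12 and 48), chromosome 12 from 115 to 120 Mb (18 and 61), chromosome 8 from 15 to 20 Mb (23 and 60) and chromosome 1 from 160 to 165 Mb (28 and 64). The lowest were chromosome 6 from 40 to 45 Mb (11 and 5), chromosome 19 from 25 to 30 Mb (24 and 14), chromosome 1 from 130 to 135 Mb (37 and 27), chromosome 2 from 165 to 170 Mb (72 and 53) and chromosome 6 from 70 to 75 Mb (38 and 28).

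The segment of chromosome 3 from 55 to 130 Mb, picked as the strongest excess, had 1.93 times as many RANKL peaks as peaks without RANKL. Over 221 autosomal runs of 15 windows outside it the highest ratio was 1.447 (1.23 with peaks closer than 1 kb merged, against 1.63 in the segment), while on chromosome X a run from 75 to 150 Mb reached 2.44 on 45 and 110 peaks (interval 1.71 to 3.54), or at most 1.41 in any run once the window from 120 to 125 Mb was left out. Uneven counts in windows placed without regard to their neighbours are argued against. Of 100 shuffles of the windows, 0 gave a run with as large a likelihood ratio (34.7, highest shuffle 16.9). The segment held 6.28 peaks per Mb without RANKL (interval 5.73 to 6.87), against 3.70 in the median window. That density cannot decide whether the excess goes with site-poor stretches. The likelihood ratio grows with the number of peaks, so the scan favours dense runs. Windows within the segment held from 0 to 84 peaks without RANKL. A candidate explanation is a higher copy number of the segment in the RANKL culture than in the other, but RANKL-responsive sites spread over the segment cannot be told apart from it, since 14 of the 15 windows, all that held peaks, lay above the genome ratio and each condition had 1 library. Peaks without RANKL had a RANKL peak more often in the segment than elsewhere both in the lower 50% by score (56.49% against 37.5%) and in the upper 50% (93.1% against 82.7%), which decides nothing because the segment was picked for its RANKL peaks.

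Of the 5931 sites with 1 peak in each list, 100% were narrower with RANKL, although single RANKL peaks elsewhere were as wide as 7463 bp. The 5th percentile of the width ratio at these sites was 2.589 and the 95th was 12.4. This cannot decide whether RANKL narrowed only some of them. Settings that differed between the lists would raise the ratio at sites that RANKL left unchanged too. Even the 7 sites at a score of exactly 3100 in both lists differed by a median of 3.18 times. This is consistent with calling or library settings that differed between the lists. A narrowing of all these sites by RANKL stays open as well, as it was not tested.

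Of the 50 RANKL-only peaks with the highest scores, 66% lay in clusters (interval 52.2 to 77.6%), against 5.84% of all RANKL-only peaks. Of the 329 clustered peaks, 8.815% (interval 6.21 to 12.4%) lay within 1 kb of a peak without RANKL, against 2.77% of all RANKL-only peaks. Whether some clustered peaks are pieces of broad open stretches called more narrowly stays open, because peaks inside a broad peak are by definition not RANKL-only. Sequence present in many copies, which can gather reads from elsewhere, may account for the clusters, but it cannot be told apart from a response to RANKL because no mm9 sequence was used.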
